A study of Mus musculus with 7 samples.

How the data were processed

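The study measured messenger RNA in laryngeal tissue of C57BL/6 mice, a common inbred laboratory strain. Libraries were made from 7 samples, 4 from Mmrn2 knockout mice (Mmrn2-/-) and 3 from wild-type mice. Per the labels' protocols, total RNA was extracted with TRIzol, its integrity was checked on a Bioanalyzer, poly(A) RNA was purified, and libraries made with the Illumina TruSeq RNA kit were sequenced on a HiSeq 2000. The labels name no age, sex, litter or batch, and do not say whether a library came from 1 animal or from several.

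The authors deposited 1 table with a gene symbol, a locus, 1 FPKM value per genotype, a log2 fold change, a p-value and a q-value per gene. FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library) is a normalized level and not a count, so the depth of each library is unknown from the deposited table, and no interval based on read counts was computed. TopHat2, a spliced-read aligner, Cuffdiff, a program that compares transcript levels between groups, and the mouse genome build mm10 are named in the submitters' processing notes, without versions or settings. How the 4 and 3 libraries were combined into 1 FPKM value per group, and how the spread between libraries entered the authors' p-values, is not given in the sources used here. Values per library were not analysed here, so no SD, no n per value, no leave-one-out and no new test between the groups are given.

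The deposited table was examined before use. It held 23996 rows with a gene, of which 106 named several genes joined by commas; 1 further line was empty, and its gene is not reported here. The deposited log2 values differed from the log2 ratio of the FPKM columns, knockout over wild type, by at most 0.00613. In 615 rows, all with FPKM 0 in the knockout group and above 0 in the wild-type group, the deposited log2 cell held a spreadsheet error in place of minus infinity; 554 rows had FPKM 0 in the wild-type group only and 5684 in both groups. A p-value of 1 stood in 10749 rows. The deposited q-values differed from Benjamini-Hochberg values over the 13247 rows with p under 1 by at most 1.21e-05. The smallest p was 5e-05, shared by 3699 rows, and the smallest q was 0.000179. A locus was shared with at least 1 other row in 5319 rows, which happens where neighbouring or overlapping genes were bundled, so such loci are wider than the gene. Start coordinates plus 1 equalled the start in the GENCODE M21 annotation (GRCm38, the assembly of mm10) for 30.9% of 22579 symbols and start coordinates as written for 3.09%, so starts were taken as counted from 0 and are printed plus 1.

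A gene is called higher or lower where the q of the authors' deposited table was under 0.05. Genes at FPKM 1 or more in the higher group were analysed, 12815 rows. The design fixed before the data were examined foresaw a limma fit on values per library and, for a table with group values only, a description of the authors' own columns. The table held group values, so the second applied. The genes named one by one follow a rule fixed at the same time: Mmrn2; the 12 genes with the largest rise and the 12 with the largest fall among called genes at FPKM 1 or more in the higher group; and up to 4 genes of each list with the smallest p, ties going to the larger change. Other genes named in the text, list members or not, were chosen after their values were seen.

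The 39 gene lists, for tissue components, neighbouring organs, blood and immune cells and signalling pathways, were fixed before the data were examined. Of 703 listed symbols, 16 were matched through a RefSeq synonym and 10 matched no single row. For each list, called members were counted over all genes, and the deposited p-values were also adjusted over the list alone. The median of log2((knockout FPKM + 1)/(wild-type FPKM + 1)) over members was set beside medians of 10000 random lists of the same size, each member replaced by 1 of the 200 genes nearest in mean FPKM. A list was called above or below its matched lists outside their central 95%, and lists with under 5 members at FPKM 1 were not compared. These percentiles describe this pair of group values and are not p-values between genotypes. For the lists, the design fixed beforehand named set tests on values per library. The comparison with random lists was not named in that design. The pseudocount of 1 understates changes of low genes.

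Transcript length and GC content were taken from the longest transcript of each symbol in GENCODE M21, coding transcripts first, and 99.3% of the analysed rows had a value. On simulated data for this comparison with 12727 genes and lists of 20 genes, the matched-list comparison called 6 of 100 unchanged lists, 96 of 100 lists shifted by 0.2 and 100 of 100 shifted by 0.4 on the log2 scale. With a simulated length trend and lists of long genes without a shift of their own, matching on mean FPKM called 89 of 100 lists, and matching on mean FPKM and length called 6 of 100. The simulated genes varied independently and list members were drawn at random, whereas genes of 1 cell type can move together. These rates therefore do not carry over to the fixed lists. Of 32 fixed lists compared, 11 lay above and 8 below lists matched on mean FPKM.

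Alternatives planned before the data were examined and computed here were a pseudocount of 0.1, no filter on low values, rescaling by the median ratio, quantile normalization, a q under 0.1 and an absolute log2 of at least 1. Chosen after seeing the data were random lists matched on transcript length, GC content or both, and subtraction of a lowess trend (span 0.3) on length or GC content. Lists of 20 markers of pregnant uterine lining, 15 of yolk sac and liver and 10 of lung alveolar epithelium were also written after the largest changes had been seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.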

Results

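The comparison addressed how loss of Mmrn2 alters gene expression in the larynx, an organ whose shape changed in the mutant mice under study. Mmrn2 encodes multimerin 2, an endothelial extracellular matrix glycoprotein of the EMILIN/multimerin family. Poly(A) RNA of 4 Mmrn2 knockout and 3 wild-type laryngeal samples was sequenced, and the authors deposited 1 FPKM value per genotype. The labels do not say whether the samples of a genotype came from separate animals, so the deposited p-values may measure a spread that is partly technical. Depth per library is unknown, and no value below carries an SD because the values are the authors' group values. The short RNA Mir6236 held 13.7% of the summed FPKM of the wild-type group and 23.8% of that of the knockout group. FPKM divides by transcript length, so a short RNA weighs heavily in such a sum. Whether these reads reflect its expression or the preparation of the libraries was not tested.

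Mmrn2 (mm10, chromosome 14, 34375504 to 34404286) fell from 3.36 FPKM in the wild-type group to 0.367 FPKM in the knockout group, 10.9% of the wild-type value, with q = 0.000179 in the authors' deposited table. Which part of the gene was deleted is not stated in the labels, so the remaining 0.367 FPKM cannot be assigned to a transcript. Of the 8 members of the list holding the EMILIN/multimerin family and the binding partners of multimerin 2, 3 were called higher and 3 lower in the authors' deposited table. The targeted gene Mmrn2 is itself a member and is among the 3 lower. Mmrn1, a second multimerin, fell from 1.47 to 0.869 FPKM, and Clec14a, an endothelial receptor that binds multimerin 2, fell from 3.68 to 2.68 FPKM. Emilin1 rose from 99.6 to 127 FPKM, Cd93 from 8.30 to 10.1 FPKM and Cd248 from 44.5 to 52.7 FPKM. Emilin2 and Emilin3 passed no threshold, with q of 0.199 and 0.925 in the authors' deposited table. Adjusted over the list alone, 6 of the 8 members passed, Mmrn2 among them.

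At FPKM 1 or more in the higher group, 12815 genes were compared, and the authors' deposited table called 6343 of them (49.5%) at q under 0.05, 3363 higher and 2980 lower in the knockout group. Most of these differences were small. The median absolute log2 change of called genes was 0.23, and 3701 of them (58.3%) changed by less than 1.2-fold. Changes of at least 2-fold were called for 22 genes higher and 98 genes lower, and changes of at least 1.5-fold for 107 genes higher and 468 lower. Across genes, log2(FPKM + 1) of the groups correlated with r = 0.97, where genes are not independent replicates. The median log2 difference of all compared genes was 0.0027.

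Most of the 12 largest called rises were genes under 1 FPKM in the wild-type group, the exceptions being Prap1 and Spp1. Prap1, which encodes a secreted acidic protein of epithelia, rose from 1.27 to 122 FPKM, a 96.2-fold difference. C3, the central complement component, whose locus was bundled with another gene, rose from 0.264 to 5.29 FPKM, and Napsa, an aspartic protease of lung and kidney epithelia, rose 7.45-fold from 0.562 to 4.18 FPKM. Klk1 (a kallikrein), Car4 (a membrane carbonic anhydrase), Cuzd1 and Serpina1e (a serum protease inhibitor) were listed at 0 in the wild-type group and at 4.33, 1.75, 1.64 and 1.13 FPKM in the knockout group. Abcb1b, Havcr1, Gkn2, Hsd11b1 and Spp1 rose between 3.78-fold (Spp1, osteopontin, 1.98 to 7.47 FPKM) and 5.91-fold (Abcb1b, a drug-efflux transporter, 0.305 to 1.80 FPKM). The authors' deposited table gave q = 0.000179 for each of the 12 except Gkn2, with q = 0.0386.

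The 12 largest called falls held Mmrn2 itself, genes of neutrophils, and genes from other sources. Stfa2, a stefin protease inhibitor of myeloid cells, was listed at 5.89 FPKM in the wild-type group and at 0 in the knockout group. Stfa1 fell from 12.2 to 1.75 FPKM, Stfa3 from 8.87 to 1.07 FPKM and Stfa2l1 from 7.19 to 1.03 FPKM; these stefins are near-identical neighbours on chromosome 16, so the split of reads among them is uncertain. Ngp, Ltf and Pglyrp1, which encode neutrophil granule proteins, fell 5.38-fold, 5.93-fold and 5.94-fold. Myl3, a ventricular and slow-muscle myosin light chain, fell 15.7-fold from 3.75 to 0.239 FPKM. Ccl11, the eosinophil chemokine eotaxin, fell 6.42-fold from 1.76 to 0.274 FPKM, and Wnt2, a mesenchymal Wnt ligand, fell 5.96-fold from 2.29 to 0.384 FPKM. Uty, a Y-linked gene, fell 5.87-fold. The q of the 12 in the authors' deposited table lay between 0.000179 and 0.0401.

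**Figure D1:**
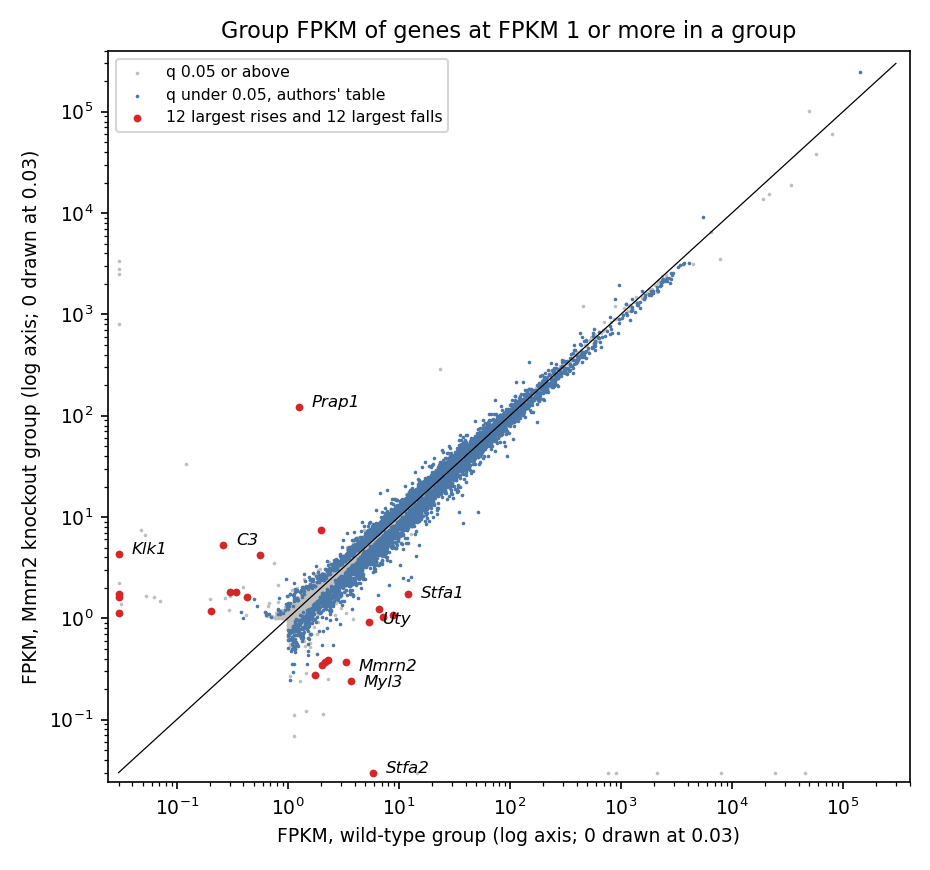
FPKM of each gene in the knockout group (vertical, log axis) against the wild-type group (horizontal, log axis), for the 12815 genes at FPKM 1 or more in a group; blue points have q under 0.05 in the authors' deposited table, red points are the 12 largest rises and 12 largest falls, and values of 0 are drawn at 0.03. Prap1 stands at 122 against 1.27 FPKM and Mmrn2 at 0.367 against 3.36 FPKM.

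Cartilage genes were higher in the knockout group. Of 19 list members at FPKM 1, 16 were called higher and 2 lower in the authors' deposited table, and 18 passed when adjusted over the list alone. Col2a1, the main cartilage collagen, rose from 115 to 215 FPKM (1.88-fold), Col11a2 from 3.45 to 6.88 FPKM (1.99-fold), Acan, the cartilage proteoglycan aggrecan, from 0.968 to 2.43 FPKM (2.51-fold) and Susd5 from 6.22 to 11.6 FPKM (1.87-fold). Sox9, the transcription factor of chondrocyte identity, rose from 59.3 to 83.9 FPKM. Hapln1, which encodes the link protein of aggrecan, fell from 1.98 to 1.62 FPKM. The median log2 difference of the list was 0.42, above all 10000 random lists matched on mean FPKM, whose central 95% ran from -0.11 to 0.09. The list of hypertrophic cartilage and bone had 6 members at FPKM 1, of which 3 were called higher and 1 lower in the authors' deposited table. Spp1 and Runx2 (2.02 to 2.76 FPKM) were among those that rose. Adjusted over the list alone, 4 members passed, 3 higher and 1 lower. Phex, an endopeptidase of bone, fell from 1.39 to 1.01 FPKM, and its log2 difference turned to 0.02 after a GC content trend was subtracted. The list median of 0.16 was at percentile 99.1 of matched lists.

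Basement membrane genes were also higher, with 17 of 18 members called higher and 0 lower in the authors' deposited table (17 adjusted over the list alone). Hspg2, the heparan sulfate proteoglycan perlecan, rose to 28.0 FPKM in the knockout group, 199.6% of the wild-type value, Lama2, a laminin chain, from 3.12 to 5.91 FPKM, Col15a1 from 14.8 to 23.8 FPKM and Col4a2 from 40.6 to 63.9 FPKM. The list median was 0.47, above all 10000 matched lists. The list of fibrous extracellular matrix divided. Of 36 members, 25 were called higher and 9 lower in the authors' deposited table (34 adjusted over the list alone), with a median of 0.25, again above all matched lists. Fn1, fibronectin, rose from 72.9 to 143 FPKM, Tnc, tenascin C, from 24.3 to 45.9 FPKM, Fbn2, a fibrillin, from 48.6 to 89.1 FPKM and Col1a2 from 235 to 329 FPKM. Postn, periostin, fell from 94.5 to 40.3 FPKM, Mfap5, a microfibril protein, from 2.94 to 0.884 FPKM, and the small proteoglycans Dcn and Lum from 88.0 to 55.3 FPKM and from 80.9 to 54.4 FPKM. Among matrix-remodelling genes 7 of 18 were called higher and 1 lower in the authors' deposited table (8 adjusted over the list alone). Mmp2, a gelatinase, rose from 112 to 155 FPKM, and Adamts5, an aggrecanase, fell from 2.22 to 1.66 FPKM.

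Across all genes, transcript length and GC content moved with the direction of change. The median log2 difference was -0.17 for 739 genes with a longest transcript under 1 kb, -0.06 for 2474 genes of 1 to 2 kb, 0.01 for 5043 genes of 2 to 4 kb, 0.07 for 3766 genes of 4 to 8 kb and 0.09 for 705 genes over 8 kb. Of genes called in the authors' deposited table, 4.17% were higher in the shortest class and 68.6% in the longest. The fifth of genes with the lowest GC content, up to 44.5% GC, had a median of -0.19, against 0.01 to 0.06 in the other four. Ribosomal protein genes, with a median transcript of 926 nt, had 55 of 76 called lower and 0 higher in the authors' deposited table. The fibrous matrix members over 4 kb had 19 of 22 called higher and a median of 0.43, whereas those up to 4 kb had 6 of 14 higher, 6 lower and a median of 0.02. Cartilage members up to 4 kb had 7 of 9 called higher and a median of 0.37, against 9 of 10 and 0.59 over 4 kb, and every basement membrane member at FPKM 1 was over 4 kb. Against random lists matched on mean FPKM, length and GC content together, the cartilage, basement membrane and fibrous matrix medians still lay above all 10000 lists. The matrix remodelling median, at percentile 99.2 of lists matched on mean FPKM alone, was at percentile 92.7 and so within the central 95%. Its difference from matched lists was 0.12, and 0.074 without the filter on low values.

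**Figure D2:**
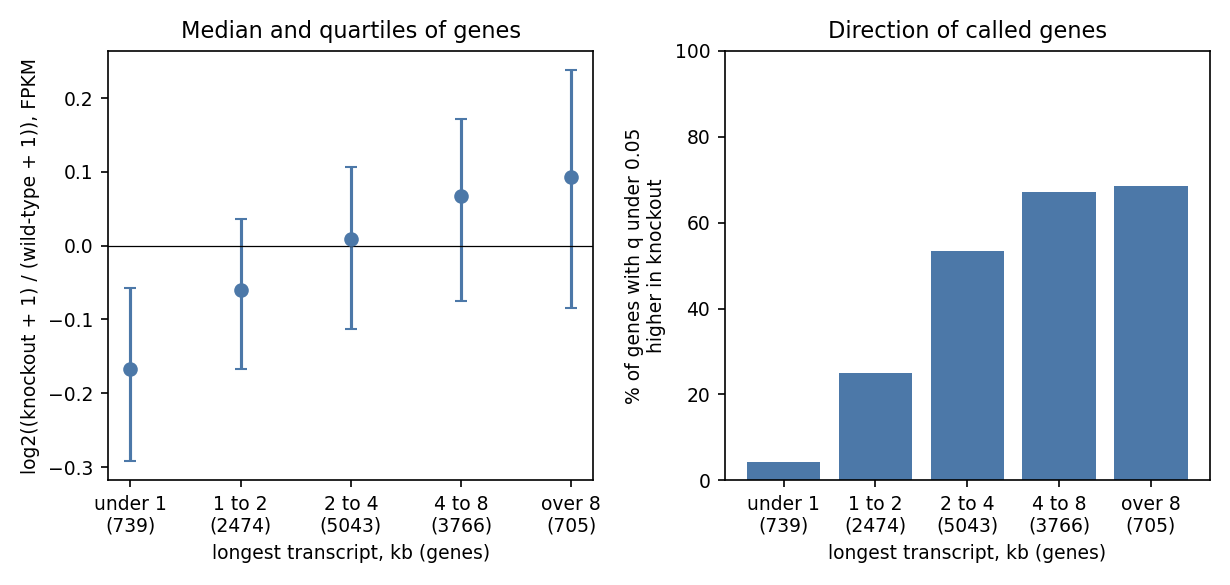
Left, median (points) and quartiles (bars) of the log2 ratio of knockout to wild-type FPKM, each plus 1, by class of longest transcript in kb, with the number of genes in brackets; right, the percentage of genes called in the authors' deposited table that were higher in the knockout group. The median went from -0.17 in the class under 1 kb to 0.09 in the class over 8 kb.

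Smooth muscle genes were lower in the knockout group. Of 13 members of the smooth muscle and pericyte list, 10 were called lower and 3 higher in the authors' deposited table (13 adjusted over the list alone). Myh11, the smooth muscle myosin heavy chain, fell from 14.2 to 4.09 FPKM (3.48-fold), Cnn1, calponin, from 10.3 to 3.37 FPKM (3.06-fold), Myocd, a transcriptional coactivator of the smooth muscle programme, from 2.98 to 1.45 FPKM and Tagln from 31.0 to 15.4 FPKM. Acta2 fell from 138 to 96.8 FPKM. Pericyte markers went both ways. Rgs5 fell from 7.54 to 4.16 FPKM, Kcnj8 from 14.9 to 9.04 FPKM and Abcc9 from 6.39 to 4.88 FPKM, whereas Cspg4 rose from 4.54 to 7.34 FPKM, Pdgfrb from 23.6 to 33.8 FPKM and Notch3 from 26.3 to 37.9 FPKM. The list median of -0.51 lay below all 10000 matched lists, with or without length and GC content in the match. Of members over 4 kb, 3 of 8 were called higher and 5 lower, with a median of -0.23, and of those up to 4 kb, 0 of 5 were called higher and 5 lower, with a median of -0.66.

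Striated muscle genes went both ways. In the fast-muscle list 8 of 17 members were called higher and 7 lower in the authors' deposited table, and in the slow-muscle list 2 of 11 higher and 3 lower (15 and 5 adjusted over the list alone). The fast-muscle list had a median of 0.09 but a mean of -0.01, and the slow-muscle median of -0.10 lay within its matched lists. Neb, the giant thin-filament protein nebulin, rose from 2.24 to 3.69 FPKM and Atp2a1, the fast-muscle calcium pump, from 13.1 to 18.9 FPKM, while Mylpf, a fast myosin light chain, fell from 374 to 265 FPKM. Of 16 members of the list of myogenic and developing muscle, 10 were called higher and 0 lower (10 adjusted over the list alone), among them the embryonic and perinatal myosins Myh3 (34.5 to 57.3 FPKM) and Myh8 (5.56 to 8.89 FPKM). The median of this list, 0.15, was at percentile 99.8 of lists matched on mean FPKM and at 99.95 with length and GC content in the match. The fast-muscle median was at percentile 96.5, within the central 95%, and at 99.4 with length and GC content in the match. Over these 3 lists together, 11 of 11 genes with a transcript over 4 kb were called higher in the authors' deposited table, against 9 higher and 10 lower of 33 shorter genes.

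Endothelial genes, the cell type in which Mmrn2 is mainly expressed, went both ways. Of 23 blood endothelial members, 7 were called higher and 8 lower in the authors' deposited table (15 adjusted over the list alone). The list median of 0.06 lay within the matched lists, and the mean was -0.04. Emcn, a sialomucin of capillaries and veins, fell from 15.3 to 9.10 FPKM, Egfl7 from 20.1 to 15.5 FPKM and Tek, the angiopoietin receptor, from 3.94 to 3.10 FPKM. Cdh5, VE-cadherin, rose from 23.9 to 29.2 FPKM and Kdr, the main VEGF receptor, from 9.42 to 11.4 FPKM. In the list of VEGF, angiopoietin and Notch vessel signalling 7 of 22 members were called higher and 7 lower in the authors' deposited table (14 adjusted over the list alone). Hey2, a Notch target of arteries, fell from 2.26 to 0.807 FPKM, Angpt1 from 3.21 to 1.83 FPKM and Angpt2 from 1.52 to 0.887 FPKM, and Notch1 rose from 8.49 to 11.3 FPKM. Of 4 lymphatic members at FPKM 1, 2 were called higher and 1 lower (3 adjusted over the list alone).

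Macrophage, neutrophil and cytokine genes were lower. All 12 members of the macrophage and dendritic cell list at FPKM 1 were called lower in the authors' deposited table, with a list median of -0.41 (12 adjusted over the list alone). The complement genes C1qa, C1qb and C1qc fell 1.55-fold, 1.70-fold and 1.60-fold, and Mrc1, the mannose receptor, fell 1.46-fold. Of 7 neutrophil and myeloid precursor genes, 6 were called lower and 0 higher (6 adjusted over the list alone), and the list median was -1.48. S100a8 and S100a9, which encode the calprotectin subunits, fell from 51.7 to 11.3 FPKM and from 37.7 to 8.70 FPKM. Of 8 cytokine and chemokine genes 5 were called lower and 0 higher in the authors' deposited table (5 adjusted over the list alone), among them Cxcl13, the B-cell chemokine (2.56 to 0.551 FPKM), and Il33 (2.23 to 1.49 FPKM). The cytokine median minus that of matched lists was -0.46 over these 8 members, and -0.073 without the filter on low values over the members of the list above 0. The pseudocount of 1 pulls the differences of members under FPKM 1 towards 0. These 3 list medians lay below at least 99.9% of matched lists under both ways of matching. Erythroid genes moved the other way, with 5 of 7 called higher and 0 lower in the authors' deposited table (5 adjusted over the list alone) and a median of 0.60. Slc4a1, the red cell anion exchanger, rose from 6.75 to 17.1 FPKM, Alas2, the first enzyme of erythroid heme synthesis, 2.03-fold and Hbb-bt from 429 to 652 FPKM; the globin genes have near-identical copies, so their individual values are uncertain. Few lymphocyte, thymus, mast cell and interferon genes reached FPKM 1. Of 2 lymphocyte members 1 was called lower, the 1 thymus member was not called, both of 2 mast cell members were called higher, and 1 of 4 interferon members was called lower and did not pass when adjusted over the list alone.

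Of 15 markers of thyroid and parathyroid, which adjoin the larynx, 5 reached FPKM 1. All 5 were called lower in the authors' deposited table (5 adjusted over the list alone): Iyd, the iodotyrosine deiodinase, fell from 1.84 to 0.445 FPKM, Pax8 from 1.91 to 0.748 FPKM, Slc26a7 from 3.48 to 2.28 FPKM, Foxe1 from 11.5 to 7.72 FPKM and Calca from 2.39 to 0.963 FPKM. The median log2 difference of these 5 minus that of matched lists was -0.70. Without the filter on low values it was -0.011, within the central 95%. The members so added lie under FPKM 1, where the pseudocount of 1 pulls differences towards 0. In the nerve and Schwann cell list 5 of 10 were called lower and 1 higher in the authors' deposited table (6 adjusted over the list alone). Sox10, a transcription factor of glia, fell from 9.11 to 6.74 FPKM. Among squamous epithelial genes 1 of 12 was called higher and 2 lower; Krt15, a basal keratin, fell from 99.4 to 67.4 FPKM, whereas Krt5 stood at 28.0 and 26.3 FPKM with q = 0.0673 in the authors' deposited table. Of 2 ciliated airway members 1 was called lower, and of 3 secretory airway members 2 were called lower. In the adipose list 4 of 8 were called higher and 2 lower, and its median of 0.17, at percentile 98.6 of matched lists, lay within their central 95% without the filter on low values. In the brown adipose list 0 of 5 were called, and in the tendon list 1 of 6 was called higher and 2 lower.

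Genes of larynx and foregut patterning were more often called higher, 12 of 23 against 4 lower in the authors' deposited table (16 adjusted over the list alone), with a median of 0.13 at percentile 99.6 of matched lists. Tbx5 and Tbx3, T-box factors, rose from 9.55 to 14.6 FPKM and from 15.6 to 21.8 FPKM. Osr1 fell from 48.9 to 33.5 FPKM and Nkx2-1, a factor of lung and thyroid, from 10.5 to 7.59 FPKM. In the TGF-beta and BMP list 11 of 23 were called higher and 4 lower in the authors' deposited table (17 adjusted over the list alone). Ltbp1, which binds latent TGF-beta, rose from 27.4 to 42.7 FPKM and Tgfbi from 105 to 142 FPKM, whereas Bmpr1a, a BMP receptor, fell. The median of this list, at percentile 98.7 of lists matched on mean FPKM, was at percentile 90.5 with length and GC content in the match, and without the filter on low values it also lay within the central 95%. Glycolysis genes had 12 of 15 called higher and 0 lower in the authors' deposited table (13 adjusted over the list alone), led by Hk2 (9.49 to 14.6 FPKM), Slc2a1, a glucose transporter (32.0 to 43.6 FPKM), and Pkm (450 to 599 FPKM). Oxidative phosphorylation genes had 18 of 30 called lower and 4 higher (24 adjusted over the list alone), with Ndufa4 at 482 and 372 FPKM; this list, at percentile 0.88 on mean FPKM alone, was at 7.98 with length and GC content in the match. In the proliferation list 10 of 20 were called higher and 5 lower, in the stress list 3 and 2 of 17, in the unfolded protein response list 4 and 9 of 17 and in the circadian list 4 and 1 of 14, and these 4 medians lay within their matched lists.

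**Figure D3:**
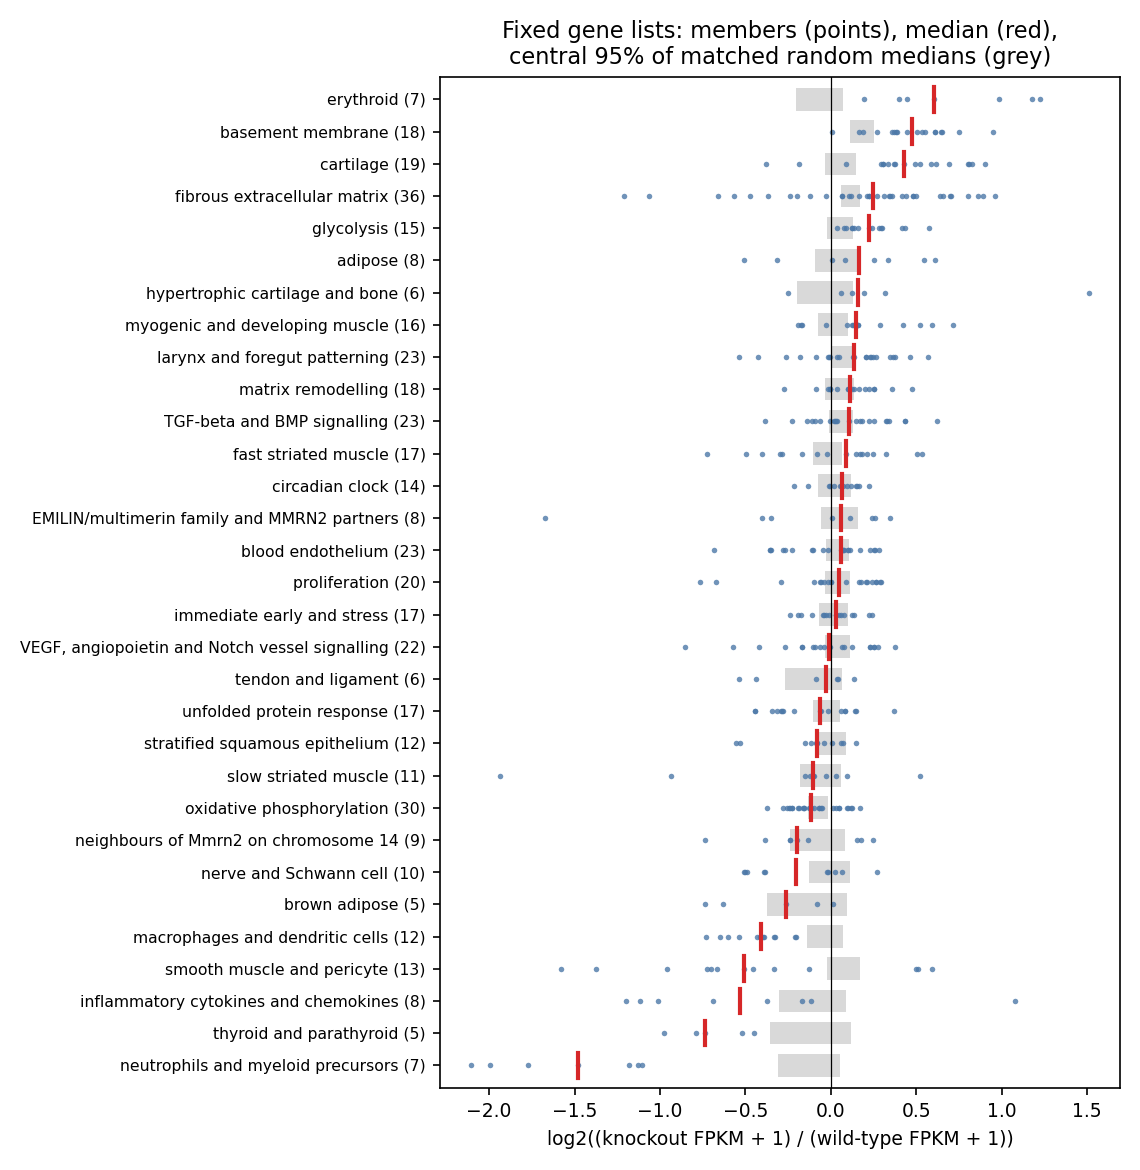
Log2 ratio of knockout to wild-type FPKM, each plus 1, for members at FPKM 1 or more (points) of each fixed gene list with at least 5 such members (number in brackets; the sex-linked list is left out), with the list median (red) and the central 95% of medians of 10000 random lists matched on mean FPKM, transcript length and GC content (grey). Cartilage and basement membrane medians of 0.42 and 0.47 lie to the right of the grey range, and smooth muscle and neutrophil medians of -0.51 and -1.48 to the left.

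Sex-linked genes differed between the groups. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty fell from 12.2 to 2.40, from 12.9 to 2.56, from 10.8 to 2.49 and from 5.44 to 0.927 FPKM, and Xist, the RNA of the inactive X chromosome, rose from 14.4 to 17.4 FPKM, each with q = 0.000179 in the authors' deposited table. Both groups held Y-linked and Xist transcripts, in different proportions.

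Genes near Mmrn2 on chromosome 14 were checked as a fixed list. Of 9 members, 6 were called lower and 2 higher in the authors' deposited table, and all 9 passed when adjusted over the list alone. Sncg, at 34370274 to 34374669 on the side before the Mmrn2 start, fell from 6.02 to 3.21 FPKM, and Bmpr1a, a BMP receptor at 34411068 to 34502546 beyond its end, fell from 47.6 to 36.1 FPKM. Further away, Wapal fell from 17.8 to 14.9 FPKM and Mapk8 from 6.79 to 5.78 FPKM, while Glud1 rose from 53.1 to 59.2 FPKM. The log2 difference of Mapk8 turned to 0.05 after a GC content trend was subtracted. The list median of -0.20 was at percentile 0.60 of lists matched on mean FPKM and at 5.18 with length and GC content in the match. Its difference from matched lists was -0.20, and -0.11 without the filter on low values.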

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

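The pseudocount of 0.1, the absence of a filter, rescaling, quantile normalization and the fold and q thresholds were planned; matching on transcript length or GC content and subtraction of their trends were chosen after seeing the data. No paired analysis was possible because the deposited columns hold 1 value per genotype and carry no replicates, and for the same reason leave-one-out, library weights, the limma trend and robust settings and set tests with an estimated correlation were not run. Median-ratio rescaling multiplied all genes by 1 factor close to 1 and so tested nothing. Quantile normalization turned the direction of 30 called genes, the length correction 120 and the GC correction 396. An absolute log2 of at least 1 left 22 genes higher and 98 lower, by construction. For lists, the value is the median minus that of matched lists. Lists that moved inside the central 95% were matrix remodelling (0.0779 matched on GC content, 0.0584 on both properties), TGF-beta and BMP (0.0591 without a filter, 0.064 on length, 0.0469 on both), adipose (0.0206 without a filter, 0.1212 on both), thyroid (-0.011 without a filter), oxidative phosphorylation (-0.0536 on length, -0.0432 on both) and the Mmrn2 neighbours (-0.1248 on GC content, -0.1531 on both). Lists that moved outside were fast muscle (0.1342 with the pseudocount of 0.1, 0.1179 with quantile normalization, 0.1614 on length, 0.1128 on both), squamous epithelium (-0.1126 on GC content), brown adipose (-0.2709 with quantile normalization) and nerve (-0.1389 without a filter, -0.173 on length, -0.2057 on GC content, -0.203 on both). Fast muscle went the other way without a filter, from 0.1037 to 0.0255, and stayed inside the central 95%. Direction reversed after the GC correction for Phex (0.0197), Tekt1 (-0.0436), Ppargc1a (0.1092), Ifit2 (0.0365) and Mapk8 (0.0537), after the length correction for Tnnc1 (0.0517), Prox1 (-0.0456), Dsp (-0.021) and Cd1d1 (0.0145), and with quantile normalization for Cd1d1 (0.0115). Apart from the fold threshold, the cause was not tested. The unknown depth leaves the precision of low FPKM values open.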

Other observations

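Matching on length and GC content together and the globin comparison were tests chosen only after the results were seen, and the marker lists of other tissues were written after the largest rises were known. Matching on length or GC content alone was likewise chosen after seeing the data. The combined sets of lists below were formed from lists already seen to differ.

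Embryonic globin genes were higher in the knockout group in the authors' deposited table. Hba-x rose from 961 to 1938 FPKM, Hbb-y from 5514 to 9187 FPKM and Hbb-bh1 from 131 to 215 FPKM. Each of these genes was abundant in the wild-type group too, so embryonic globin RNA was not particular to the knockout group. The labels give no age for either group. With embryonic globin RNA this abundant in both groups, the values should not be read as those of adult larynx. Cell-cycle genes went both ways, with 10 of 20 members of the proliferation list called higher and 5 lower. Among the 4 with the smallest p in the authors' deposited table, Cenpf fell from 7.05 to 3.73 FPKM, Bub1 from 15.8 to 9.56 FPKM and Mki67 from 32.9 to 26.7 FPKM. Plk1 rose from 39.9 to 49.1 FPKM. Of the chaperones, Hsp90b1 fell from 270.1 to 198 FPKM and Sdf2l1 from 23.5 to 17.0 FPKM.

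Cartilage, basement membrane and fibrous matrix genes were higher in the knockout group, with a median log2 difference of 0.37 over 73 genes. Long transcripts were higher in general, but lists matched on mean FPKM and length had a median of 0.08, lists matched on GC content 0.02 and lists matched on both 0.12, and the observed median was at percentile 100 of each of the 3. The cartilage, basement membrane and fibrous matrix lists had each lain above all their matched lists. The percentiles of the 73 genes together were thereby all but fixed and add no separate evidence. Trends on the longest transcript may account for part of the difference, and matching on them left the rest. Such matching cannot exclude a technical cause that these properties do not capture. List by list, cartilage members up to 4 kb had a median of 0.37 and fibrous matrix members up to 4 kb a median of 0.02. No basement membrane member was that short, so for this list short transcripts could not be examined. Where the trends themselves come from was not tested, and RNA quality or library preparation differing between the groups could underlie them and many of the small calls. A larger share of cartilage in the dissected knockout tissue, a different age, different sex proportions and an effect of the genotype all stay open. The labels give no age or sex, Y-linked genes were lower in the knockout group, and values per library were not analysed here.

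The 12 largest rises were mostly near 0 in the wild-type group, and RNA of another tissue in the knockout libraries is a candidate explanation. Members at a knockout FPKM of at least 0.1 and at least 2 times wild type made up 10% of 20 uterine lining markers, 13.3% of 15 yolk sac and liver markers and 20% of 10 lung alveolar markers, at percentiles 96.5, 91.6 and 99.0 of lists matched on mean FPKM. Among the abundant genes of these tissues, Prl8a2 stood at 0.0318 and 1.39 FPKM, Afp at 0.0634 and 0.919 FPKM, Alb at 0.103 and 0.151 FPKM and Sftpc at 0 and 0.0792 FPKM, none of them called. In each of the uterine and lung lists 2 markers were called higher and 1 lower in the authors' deposited table, Ltf being the uterine marker lower; Ltf and Sftpd also stood on a list fixed earlier for the larynx and its cells. With so many markers near the lower limit of the table, these sources cannot be told apart from each other or from a change within the larynx.

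Smooth muscle, macrophage and neutrophil genes were lower in the knockout group, with a median log2 difference of -0.57 over 32 genes. Lists matched on mean FPKM and length had a median of -0.04. The observed median was at percentile 0.0 of them and at percentile 0.0 of lists matched on length and GC content. The smooth muscle, macrophage and neutrophil lists had each lain below all their matched lists, so these percentiles add no separate evidence. Matching on the longest transcript left the difference of each list in place. It cannot exclude a technical cause that length and GC content do not capture. Knockout tissue from a younger stage is a candidate explanation: embryonic globin genes exceeded adult globin genes in their log2 difference by 0.077, too little to decide, and both sets were higher, by means of 0.82 and 0.74. Of 15 thyroid and parathyroid markers, the 5 at FPKM 1 were called lower in the authors' deposited table. Without the filter on low values the list differed from matched lists by -0.011. The members so added lie under FPKM 1, where the pseudocount of 1 pulls differences towards 0. That value therefore cannot weaken the fall of these 5. A different dissection was not tested and stays open, as do different sex proportions and an effect of the genotype.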
